A study of Drosophila melanogaster with 3 samples.

How the data were processed

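The data are 3 iCLIP libraries of GFP-tagged Aubergine (Aub) from one line of cultured Drosophila melanogaster germline stem cells that lack bam function. iCLIP (individual-nucleotide crosslinking and immunoprecipitation) fixes a protein to the RNA it touches with ultraviolet light, purifies the complex and sequences the attached RNA. Per the labels, cells in 150 mm dishes received 150 mJ/cm2 of light at 254 nm. Each library carried a 4-nt experimental barcode and a 5-nt random barcode meant for finding PCR duplicates. The labels do not say that the libraries came from separate cultures, so the spread between them may be technical. All 3 form one group, numbered 1 to 3 as in their titles, and no control library was analysed here.

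The authors deposited, for each library, a list of called intervals with chromosome, start, end, strand and a FlyBase gene ID. Per the submitters' processing notes, CASAVA 1.4 and TopHat2 2.0.13 were used and the genome build was dm3. The peak caller, its threshold, the gene annotation and whether duplicates were removed with the random barcode are not given in the sources used here. The deposited score is 0 for every interval, so the intervals have no height, fold enrichment or p-value, and the depth in reads is unknown. Every interval carries a gene ID, and the intervals of a gene lie on a single strand. The profile is therefore limited to annotated genes, and a library's number of intervals stands in for its depth only indirectly. Intervals were called separately in each library.

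What was computed here started from these intervals. Rows of the same position and strand assigned to a second gene (21, 333 and 113 rows in replicates 1, 2 and 3) were counted once in analyses of position and kept in counts per gene. Positions are given 1-based on dm3. An interval counted as shared when an interval of the other library lay on the same strand within 10 nt. The shared percentage was set against 100 random placements of the intervals on their chromosome and strand. A second set of 100 placements, within the span between the first and last interval of the same gene, and shifts of 100 to 500 nt in both directions were added after the data had been seen. Shares have 95% Wilson intervals, which treat intervals as independent and cover counting error only. Correlations were computed across genes on log2 of intervals, scaled to 1000000 per library, plus a pseudocount of 1. In these units 1 interval was worth 249.6, 27.7 and 84.8 in replicates 1, 2 and 3. Genes are not independent replicates, so no p-value is given for these correlations. Intervals of all libraries joined within 50 nt on one strand formed regions. Permutation tests across genes were two-sided with 100000 resamples, or 10000 for medians and trimmed means. They treat genes as independent, so their p-values describe a single library and not the spread between replicates.

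Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap search was tested on simulated data for replicate 1 against replicate 2 (3986 intervals). It found 100% of planted shared intervals and 0.865% of randomly placed ones with 25% planted, and it gave the answer of an exhaustive search for all of 300 intervals tested. The permutation test of intervals per gene on chromosome 4, simulated for replicate 2 over 6296 genes, passed 0.05 in 20 of 20 simulations with a planted ratio of 2 and in 1 of 20 with a ratio of 1.

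The rule for named items, the descriptive comparisons, the gene list tests and most alternatives were fixed before the data were examined. The permutation tests across genes were chosen after the data had been seen. The rule took the 20 regions with the highest mean share of intervals among those with intervals in all 3 libraries, since gene names were lacking. The files pair gene IDs with no symbols. A RefSeq gene table of the Release 6 assembly listed 51 of the 6502 gene IDs (0.784%) under 1 symbol and 2 under several. These 51 are the genes named here. They were picked by the table and not by their values, and naming them was decided after the data had been seen. Of the 51, 49 lie on the same chromosome name in the files and the table, and the other 2 lie on Het scaffolds in the files. None of the members listed by symbol in the 14 fixed gene lists (among them germline stem cell self-renewal, differentiation, the piRNA pathway, translation initiation and markers of other cell types) could be matched, so the list tests are void. The genes aub, bam, nos, vas and piwi are not reported for the same reason. No annotation or sequence of the build used was at hand, so transcript parts and base composition around the sites were not analysed here.

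The alternatives were an exact shared start, a distance of 50 nt, intervals at or above the median width, strand ignored, mitochondrial intervals left out, other pseudocounts, a minimum of 10 intervals per gene, windows of 1 kb (bound in either or in both libraries), covered nucleotides in place of intervals, other joining distances, thinning to the smallest library and leaving out each library.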

Results

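Aub is a Piwi-family Argonaute protein that carries piRNAs, the small RNAs that guide silencing of transposons in the germline. The study mapped the RNAs to which Aub was crosslinked in cultured germline stem cells kept undifferentiated by the loss of bam, a gene required for their progeny to differentiate. The cells carried a GFP-Aub transgene, and no drug was given. The 3 libraries form a single group, so the comparisons are between replicates, between chromosomes and between genes.

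Replicate 1 held 4007 called intervals in 1459 genes, replicate 2 held 36157 in 6364 genes and replicate 3 held 11798 in 3310 genes. Replicate 2 thus had 9.02 times as many intervals as replicate 1 but 4.36 times as many genes. The intervals covered 84473, 642273 and 234180 nt in replicates 1, 2 and 3. Their mean width was 21.2, 17.9 and 20.04 nt, and their median width 25, 13 and 25 nt. A gene with any interval had on average 2.75 intervals in replicate 1, 5.68 in replicate 2 and 3.56 in replicate 3. The most heavily covered 10% of genes held 31.6%, 40.1% and 34.5% of the intervals. Both values can rise with the number of intervals, so they do not show that replicate 2 was the most concentrated library. Thinned at random to the 4007 intervals of replicate 1, replicate 2 fell in 2403 genes and replicate 3 in 2079, against 1459 in replicate 1.

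The first question was whether the bound genes recurred. Bound here means holding at least 1 called interval, without a control for background or transcript abundance. Genes with a single interval made up 36.2%, 26.6% and 29.8% of the bound genes in replicates 1, 2 and 3. Intervals fell in 6502 genes in all, of which 1361 were bound in all 3 libraries and 3270 in at least 2. Genes of the smaller libraries were nearly all found in replicate 2, which contained 1451 of the 1459 genes of replicate 1 (99.5%, 95% Wilson interval 98.9 to 99.7) and 3176 of the 3310 genes of replicate 3 (96.0%, 95.2 to 96.6). Replicate 3 contained 1365 of the genes of replicate 1 (93.6%, 92.2 to 94.7). Replicate 2 held 6364 of the 6502 genes, so near-complete containment in it says little about recurrence. Genes bound only in replicate 2 numbered 3098, against 4 only in replicate 1 and 130 only in replicate 3. Within replicate 2, genes bound in all 3 libraries had a mean of 14.1 intervals, genes shared with replicate 3 alone had 5.29, and genes found in replicate 2 alone had 2.22. The 1361 common genes held 53.2% of the intervals of replicate 2. Their number was limited by replicate 1, without which 3176 genes were common to the remaining pair. When replicates 2 and 3 were thinned at random to the 4007 intervals of replicate 1, 765 ± 14.1 genes (SD over 100 draws) were common to the 3 libraries. Of its 1459 genes, replicate 1 then shared 987 ± 11.8 with replicate 2 and 1039 ± 13.3 with replicate 3. Random thinning need not match what a library of lower depth would lose. Thinned replicate 2 fell in 2403 ± 21.4 genes, more than the 1459 of replicate 1.

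Of the 51 genes with a known symbol, 14 were bound in all 3 libraries. LanA, the laminin alpha chain of basement membranes, had the highest mean share of these, with 4, 20 and 6 intervals in replicates 1, 2 and 3 between positions 6196996 and 6211122 of 3L (0.069% ± 0.027 of a library's intervals, SD, n = 3). CG42353 on X followed with 3, 18 and 8 intervals (0.064% ± 0.013). CrebB, a CREB-family transcription factor gene, had 2, 14 and 5 intervals between 18261145 and 18271659 of X (0.044% ± 0.0057). Asx, a chromatin regulator of the Polycomb and trithorax systems, had 1, 17 and 6. Swim had 2, 10 and 6 and metro 3, 7 and 2. Treh, which encodes trehalase, had 2, 6 and 4 intervals. Su(var)205, which encodes a heterochromatin protein, had 2, 10 and 1 intervals between 8209755 and 8211072 of 2L. Nasp, which encodes a histone chaperone, had 1, 8 and 3, and mfas had 1, 10 and 3. Meltrin, a gene of the ADAM protease family, had 1, 10 and 2 intervals, and ScsbetaA, a subunit of succinyl-CoA synthetase, had 1, 5 and 3. CG17159 had 2, 17 and 4 intervals and lay on the XHet scaffold. The remaining member, the asparagine tRNA gene tRNA:Asn-GTT-1-7, had 1 interval in each library, of 24, 25 and 25 nt, all within positions 2077659 to 2077683 of 2R. The shares of mfas (0.0260% ± 0.0014) and Nasp (0.0242% ± 0.0018) varied least around their means. For genes with 1 or 2 intervals in replicate 1 a single interval decided the value there. The differences in mean share among these genes were not tested.

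A further 16 named genes were bound in exactly 2 libraries. For 13 these were replicates 2 and 3, among them Aldh, an aldehyde dehydrogenase gene (12 and 2 intervals), MED1, a Mediator subunit gene (9 and 2), Herc4 (8 and 3), lwr, the SUMO-conjugating enzyme gene (5 and 2), and AMPKalpha, the catalytic subunit of the energy-sensing kinase (3 and 2). For the other 3 they were replicates 1 and 2, with 4 and 3 intervals in CG33978, 2 and 5 in Spn77Bc and 1 and 1 in Coa7. These 3 had no interval in replicate 3, although it held 2.94 times as many intervals as replicate 1. The other 21 named genes were bound in replicate 2 alone. They included Dpm2 with 10 intervals, snama with 8, pps with 6, and the X-chromosome noncoding RNA gene lncRNA:roX1 with 1. Replicate 2 was the library with most intervals, so for these 21 genes absence from the others was not separable from their lower number of intervals.

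The second question was whether the same positions were bound. Of the 3986 distinct intervals of replicate 1, 2387 lay within 10 nt of an interval of replicate 2 (59.9%, 95% Wilson interval 58.4 to 61.4) and 1315 within 10 nt of one of replicate 3 (33.0%, 31.5 to 34.5). Of the 11685 distinct intervals of replicate 3, 5448 lay that close to an interval of replicate 2 (46.6%, 45.7 to 47.5). The mean of these 3 shares, each of a smaller library in a larger one, was 46.5% ± 13.4 (SD, n = 3 pairs, which are not independent). Both other libraries had an interval near 1195 intervals of replicate 1 (29.98%, 28.6 to 31.4). Random placement on the same chromosome and strand gave 0.876% ± 0.134 for replicate 1 in replicate 2, 0.402% ± 0.1004 for replicate 1 in replicate 3 and 0.799% ± 0.077 for replicate 3 in replicate 2 (SD over 100 placements). Placement within the span of the same gene gave 9.73% ± 0.39, 5.21% ± 0.30 and 9.54% ± 0.25 for these pairs. None of the 100 placements of either kind reached the observed share in any of the 6 directions tested. Both kinds are weak controls. All intervals carry a gene ID, whereas chromosome placement ignored genes, and placement within a gene's span was uniform without regard to its exons. Exceeding them therefore does not by itself show a preference of Aub for certain positions. Shifts of 100 to 500 nt left 20.6%, 9.77% and 15.7% on average, and at most 35.1%, 16.6% and 25.9%, for the same pairs. The observed shares were 2.90, 3.38 and 2.96 times the mean after shifting. The share was lower when intervals of the larger libraries were removed at random. With replicates 2 and 3 thinned to 3986 intervals it was 8.48% ± 0.39 for replicate 1 in replicate 2 and 12.8% ± 0.43 for replicate 1 in replicate 3. Between replicates 2 and 3 it was 6.41% ± 0.33 (SD over 20 draws). Random thinning drops strong and weak sites alike, which need not match what a library of lower depth would lose. Placements and shifts were not run on thinned libraries.

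**Figure D1:**
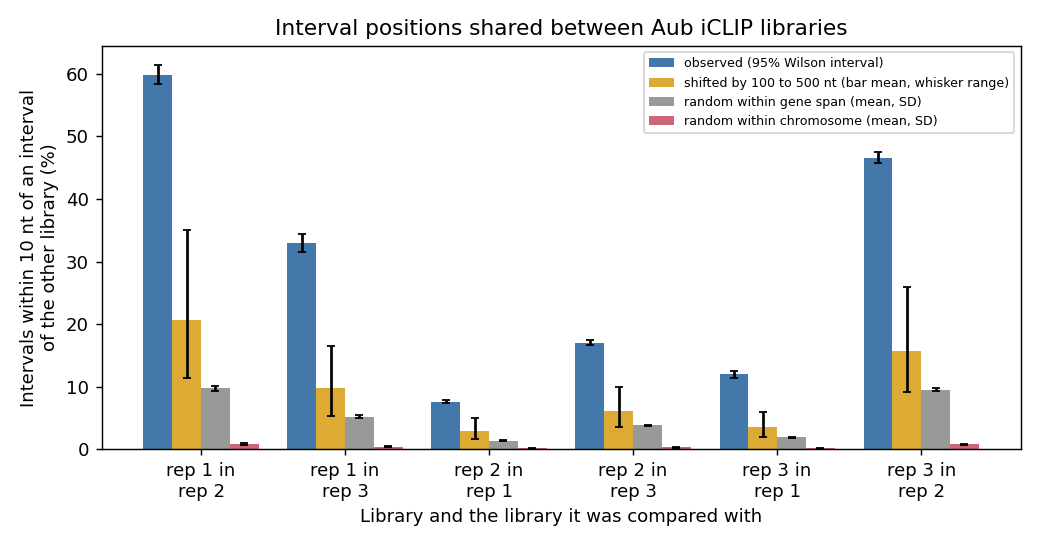
Percentage of the intervals of one library that lay within 10 nt of an interval of another (vertical axis) for each direction of the 3 pairs (horizontal axis), with the value after shifts and after random placement within genes or chromosomes. The observed share exceeded all 3 controls in each direction, from 7.60% for replicate 2 in replicate 1 to 59.9% for replicate 1 in replicate 2.

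The interval edges coincided to the nucleotide more often than at nearby offsets. For replicates 1 and 2, 205 intervals shared the 5′ edge exactly, against a mean of 41.8 and a maximum of 70 at offsets of 5 to 30 nt. The counts were 122 against 22.2 for replicates 1 and 3, and 473 against 102 for replicates 2 and 3. At 3′ edges the counts were 207 against 40.9, 147 against 21.8 and 537 against 99.5. Both edges were equal for 36, 37 and 65 intervals of these pairs, so no library repeated another. In iCLIP the 5′ edge of a read marks the nucleotide next to the crosslink. The edges here are those of called intervals and not of reads, so their coincidence need not mark crosslinked nucleotides. The excess at exact coincidence was 4.65- to 5.50-fold at 5′ edges and 5.06- to 6.75-fold at 3′ edges. It was larger at 3′ edges in each pair, and the difference between the edges was not tested.

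**Figure D2:**
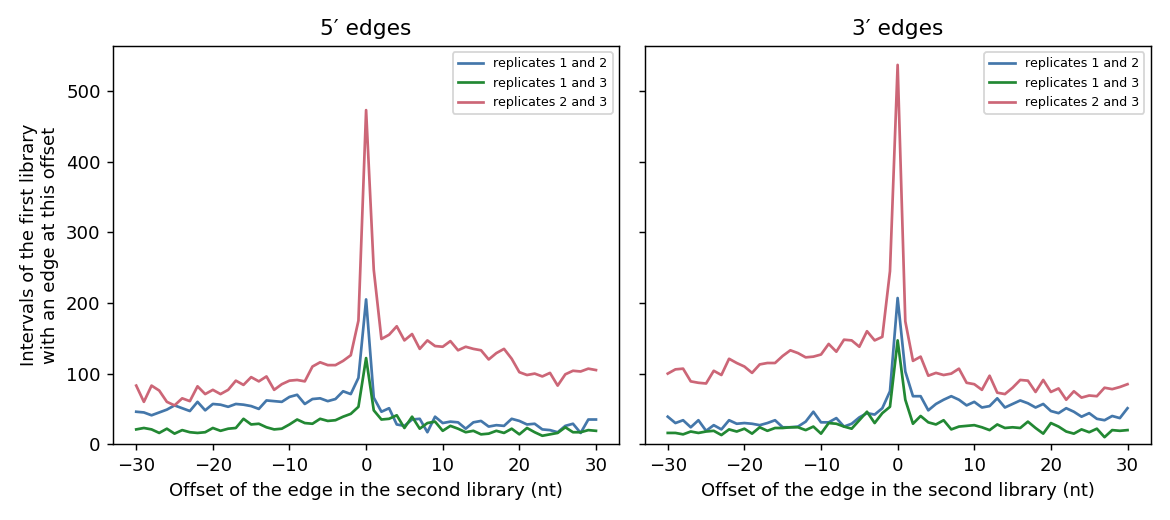
Number of intervals of the first library of a pair with a 5′ edge (left) or 3′ edge (right) of the second library at each offset from -30 to 30 nt (horizontal axis). Each pair has a single peak at offset 0, of 473 intervals for the 5′ edges of replicates 2 and 3.

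The number of intervals per gene was positively related between libraries across genes. Among genes bound in either library of a pair, Pearson's r was 0.61 and Spearman's rho 0.58 for replicates 1 and 2 over 6372 genes, 0.22 and 0.47 for replicates 1 and 3 over 3404 genes, and 0.50 and 0.66 for replicates 2 and 3 over 6498 genes. Among genes bound in both libraries, r was 0.51, 0.52 and 0.66 for the same pairs, over 1451, 1365 and 3176 genes. The mean r over the pairs was 0.44 ± 0.20 (SD, n = 3 pairs), and it was 0.22 when replicate 2 was left out. For windows of 1 kb bound in both libraries, r was 0.32, 0.43 and 0.41 for the same pairs, over 2122, 1725 and 4837 windows. Over windows bound in either library, of which 15.2%, 21.0% and 30.6% were bound in both, the mean r was -0.22. Windows with no interval in 1 library of a pair therefore gave the negative mean. Leaving out such genes raised r for replicates 1 and 3 (0.22 to 0.52) and replicates 2 and 3 (0.50 to 0.66). It lowered r for replicates 1 and 2 (0.61 to 0.51). All these values are across genes or windows, which are not independent replicates. Gene length and transcript abundance were not accounted for, so a positive relation need not reflect a preference of Aub for certain genes.

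By chromosome, X carried the largest share of intervals, 22.7% ± 1.32 (SD, n = 3), followed by 3R with 19.97% ± 1.21, 2R with 18.0% ± 0.71, 3L with 17.7% ± 0.89 and 2L with 16.6% ± 0.34. X led in each library, with 23.8%, 21.3% and 23.2% against 18.6%, 20.9% and 20.4% for 3R, and the gap was smallest in replicate 2. The small chromosome 4, much of which is packaged as heterochromatin, carried 3.02% ± 0.57. It held 3.02%, 1.12% and 1.72% of the bound genes in replicates 1, 2 and 3. Its bound genes had a mean of 3.34, 13.1 and 5.81 intervals each, against 2.50 to 2.91, 5.25 to 6.38 and 3.33 to 3.91 on the other arms. The plus strand held 49.7% ± 0.75 of the intervals.

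**Figure D3:**
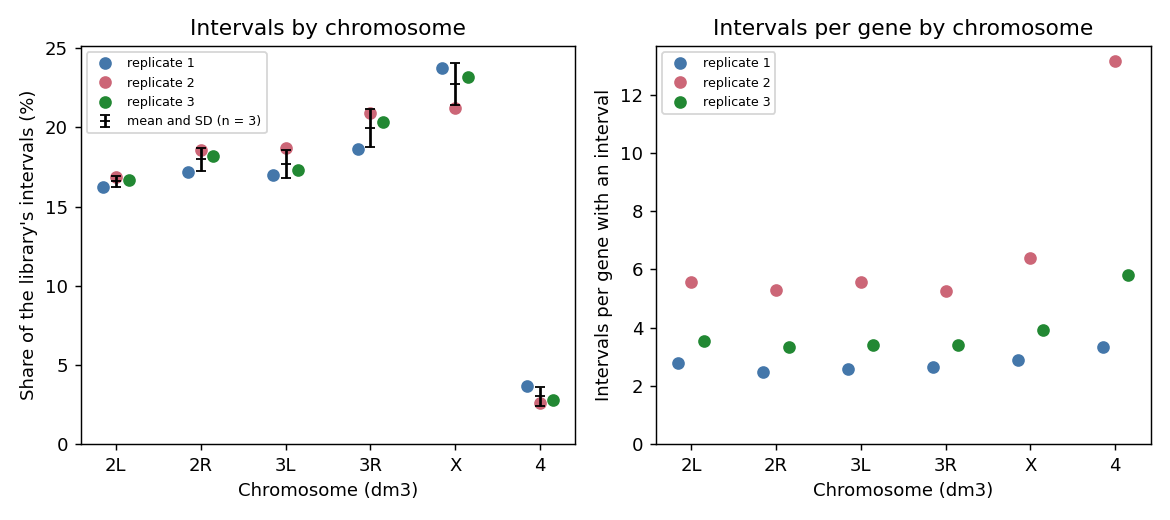
Share of a library's intervals by dm3 chromosome in percent (left, points for each replicate, with mean and SD, n = 3) and mean intervals per bound gene (right). Chromosome 4 holds 3.02% of the intervals on average but, of the chromosomes plotted, the most intervals per gene in each replicate, 13.1 in replicate 2.

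Transcripts of the mitochondrial genome contributed 38, 105 and 70 intervals in 11, 25 and 20 genes. Their shares were 0.948% (95% Wilson interval 0.692 to 1.30) in replicate 1, 0.290% (0.240 to 0.351) in replicate 2 and 0.593% (0.470 to 0.749) in replicate 3. The interval of replicate 2 lay below those of replicates 1 and 3, which overlapped. By covered nucleotides the mean share was 0.353% in place of 0.611%. The Het scaffolds, which hold unplaced heterochromatic sequence, contributed 2.55%, 0.810% and 0.814%, with a mean of 1.39% ± 1.00 (SD, n = 3) that fell to 0.812% without replicate 1. FBgn0085813 lay there, between positions 190037 and 195829 of XHet. It had 51 intervals in replicate 1, 17 in replicate 2 and 25 in replicate 3, which were 1.27%, 0.047% and 0.212% of the libraries. Its mean share was the highest of all genes (0.511% ± 0.665, SD, n = 3), but this rested on replicate 1, without which its mean share was 0.129% and its rank 40. The gene with the next highest mean share, FBgn0001234, lay between 17122373 and 17142282 of 3R and had 21, 117 and 34 intervals (0.379% ± 0.127, SD, n = 3). Without replicate 1 its mean share was 0.306% and its rank 1. Of the 25 genes with the highest mean shares, 6 lay on X, 6 on 2L, 4 on 2R, 3 each on 3L and 3R, 2 on chromosome 4 and 1 on XHet. Together they held 9.51%, 3.83% and 5.21% of the intervals of replicates 1, 2 and 3.

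Joining intervals within 50 nt gave 26114 regions, of which 1224 had intervals in all 3 libraries and 5243 in at least 2. The common number was 4389 without replicate 1 and 1981 without replicate 3. The 20 regions with the highest mean share were 261 to 658 nt long and lay in 5 cases each on X and 3R, in 4 on 3L, in 3 on 2L, in 2 on chromosome 4 and in 1 on 2R. The leading region, on the minus strand of 3R from 4756959 to 4757599, held 8, 10 and 12 intervals in replicates 1, 2 and 3 (0.110% ± 0.087, SD, n = 3). The next, on the minus strand of 2L from 21626894 to 21627352, held 6, 8 and 12. FBgn0001234 contained 2 of the 20, from 17124422 to 17125028 with 5, 16 and 12 intervals and from 17124009 to 17124365 with 5, 9 and 5. On X, the plus-strand region from 11267850 to 11268182 held 8, 8 and 4 intervals. On chromosome 4, the minus-strand region from 578069 to 578463 held 6, 19 and 6, and the plus-strand region from 90093 to 90551 held 5, 9 and 9. The region on the plus strand of 2R from 3853096 to 3853753 held 3, 19 and 7 intervals and had the smallest spread of the 20 (0.063% ± 0.011). Among the 20 regions the SD was often close to the mean share, so their order was not resolved. Without replicate 1, in which a single interval weighs most, 10 of the 20 stayed among the 20 highest.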

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

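Of 84 alternative values computed, 63 moved by less than the spread between replicates or, for counts, by less than 1.5 times. Some of these could not have moved further. Leaving out 1 of 3 libraries cannot shift a mean over libraries by 1 SD. This applies to the chromosome and strand shares and to the chromosome 4 ratio. The pseudocount cannot change a rank correlation. Thinning, windows of 1 kb, genes bound in both libraries, a pseudocount of 100, covered nucleotides, leaving out the gene with most intervals and every alternative for the ratio of intervals per gene on chromosome 4 were chosen after seeing the data. The mean shared percentage (46.5%) fell to 4.08% with an exact shared start and to 9.22% with the larger libraries thinned, and ranged from 33.0% to 59.9% with each library left out. The mean Pearson r (0.44) was 0.31 among genes with at least 10 intervals summed over the libraries and 0.66 with a pseudocount of 100. It reversed to -0.22 in windows of 1 kb bound in either library (0.39 in both). With each library left out it ranged from 0.22 to 0.61. The mean rho (0.57) was 0.45 among genes with at least 10 intervals and 0.059 in windows (0.36 in both), and ranged from 0.47 to 0.66. Windows bound in only 1 library gave the reversal. Other causes were not tested. The 1361 common genes became 800 with at least 2 intervals in each library, 3270 with 2 of 3 libraries and 765 after thinning, and 1365 to 3176 with each library left out. The 1224 common regions became 281 with at least 2 intervals in each library and 5243 with 2 of 3 libraries, and 1319 to 4389 with each library left out. Requiring more or fewer libraries changes these counts by construction. Of the 20 leading regions, 10 stayed when intervals were summed over libraries, 11 by covered nucleotides, and 10 to 18 with each library left out. The shares on X, chromosome 4, the mitochondrial genome, the Het scaffolds and the plus strand moved by less than 1 SD under every alternative run for them. For leaving out a library this holds by construction. That SD is wide for the mitochondrial share, which fell from 0.611% to 0.353% by covered nucleotides. It is also wide for the Het share, which fell from 1.39% to 0.812% without replicate 1. The mean ratio of intervals per gene on chromosome 4 (1.75 ± 0.56, SD, n = 3) also has a wide SD. It was 1.81 with an equal share of the highest genes left out on chromosome 4 and on the other arms, and 1.34 with the 5 highest genes left out on chromosome 4 alone, which lowers it by construction. Alternatives based on scores, exonic length, transcript parts, gene lists and base composition were not run, because all scores are 0 and no gene models, symbols or sequence of the build were used. No paired analysis was possible because there is a single group. Read depth is unknown, and the number of called intervals limits what replicates 1 and 3 can show.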

Other observations

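All tests in this part were chosen after seeing the data, and the joined-region and spacing tests for chromosome 4 were written down before their own values were seen.

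Bound genes on chromosome 4 had more intervals than bound genes on the other arms. The ratio of means was 1.24 in replicate 1 (adjusted permutation p = 0.082, 44 against 1383 genes), 2.35 in replicate 2 (6e-05, 71 against 6225 genes) and 1.65 in replicate 3 (0.00044, 57 against 3205 genes), with Benjamini-Hochberg adjustment over 6 tests, so it was above 1 in 3 of 3 libraries and passed the test in 2. These tests resample genes within a library and treat them as independent, which they are not, so their p-values describe each library and do not measure the spread between replicates. The unadjusted p behind the value for replicate 2, 1e-05, is the smallest that 100000 resamples can give. The median number of intervals per bound gene was 2.5 on chromosome 4 against 2 on the other arms in replicate 1. In replicate 2 it was 10 against 3, and in replicate 3 it was 3 against 2. Thinning replicates 2 and 3 to 4007 intervals gave ratios of 1.44 ± 0.13 and 1.45 ± 0.12 (SD over 100 draws). Bound genes on X, set against the autosomal arms without chromosome 4, had ratios of 1.11, 1.18 and 1.15 (adjusted permutation p = 0.08, 9e-05 and 0.0019).

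Several explanations for chromosome 4 were weighed. Splitting of one bound stretch into short intervals would not leave an excess after joining intervals within 200 nt, but the ratio of regions per gene was 1.98 in replicate 2 (permutation p = 1e-05, the smallest possible) and 1.38 in replicate 3 (permutation p = 0.0016), and it was 1.32 in replicate 1 (permutation p = 0.0092). A few heavily covered genes do not account for the excess when both sides are trimmed equally. For this, the 5 highest genes of chromosome 4 and an equal share of the highest genes of the other arms were left out. The ratio was then 2.56 in replicate 2 (permutation p = 0.0001, the smallest that 10000 resamples can give). It was 1.55 in replicate 3 (permutation p = 0.0007) and 1.31 in replicate 1 (permutation p = 0.019). Leaving out the 5 genes on chromosome 4 alone, which lowers the ratio by construction, gave 0.98, 1.86 and 1.16 in replicates 1, 2 and 3 (permutation p = 0.92, 2e-05 and 0.25). Longer genes with an equal density of intervals could not be excluded. Neighbouring regions were closer on chromosome 4 at a permutation p under 0.05 in 0 of 3 libraries. The ratios of median distance were 1.10, 0.86 and 0.73, and no gene lengths of the build were used. A candidate explanation that remains is thus gene length. The heterochromatic state of the chromosome was not tested, and no measure of transcript abundance was at hand.

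Intervals of exactly 25 nt made up 52.0%, 8.98% and 47.5% of the distinct intervals of replicates 1, 2 and 3. The number at 25 nt was 29.6, 4.38 and 31.1 times the mean of the numbers at 24 and 26 nt. A length fixed before deposit, such as a trimmed read or an extension, is a candidate explanation, but these counts are the observation itself and do not test it. It therefore stays open, as does the size of the RNA bound by Aub, and the sources used here name no such step. Intervals of up to 5 nt made up 8.58%, 28.4% and 11.2%.

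The XHet gene FBgn0085813 had more intervals in replicate 1 than in the larger libraries (51 against 17 and 25). If neighbouring intervals had run together at higher depth, at least as many nucleotides would be covered there, but coverage fell from 1021 nt in replicate 1 to 745 nt in replicate 2 and 653 nt in replicate 3 (0.73 and 0.64 times). Differences in the threshold between libraries, reads shared between repeated copies and a different RNA composition of replicate 1 stay open as untested, and the design names no biological difference between the replicates.

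Opposite-strand piRNAs whose 5′ ends overlap by 10 nt are the trace of the ping-pong cycle, in which Aub and a partner cut complementary transposon transcripts. The edges of called iCLIP intervals need not be 5′ ends of piRNAs. In replicate 2, 0 pairs of opposite-strand intervals overlapped by 10 nt at their 5′ edges. The median was 1 and the maximum 4 at the other 24 overlaps from 1 to 25 nt. With 33 pairs in all, and intervals listed on a single strand for each gene, this test had little power. Since interval edges need not be piRNA ends, it cannot decide whether the cycle was active. Intervals overlapping one on the other strand numbered 0, 93 and 2 in replicates 1, 2 and 3.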
